A study of Drosophila melanogaster with 6 samples.

How the data were processed

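RNA from flow-sorted dorsal cells of Drosophila wing discs was read by 3' mRNA sequencing in 100-nucleotide single reads, per the labels' protocols, in 3 libraries expressing RasV12 and 3 carrying GFP-i. The authors deposited 1 table with raw counts per gene for each library and the columns of their own comparison. Per the submitters' processing notes, the tools were Trimmomatic 0.33, STAR 2.3.0e, bedtools 2.17 and DESeq2 with the genome build dm6. The counting program, its strand setting and the annotation release are not given in the sources used here. The deposited counts are whole numbers and are not normalized, as found from their values. The deposited baseMean column is a signal, the mean of counts divided by size factors by the authors' DESeq2, per the file headers. The log2 fold changes and their errors are those of the authors' comparison, per the file headers, and both a shrunken and an unshrunken estimate are deposited. The deposited test statistic per gene is a score of the authors' comparison, per the file headers. The p-value and adjusted p-value columns are the authors' deposited ones, and some adjusted p-values are left blank. A further deposited column of another kind marks the authors' calls as higher, lower or neither. The table lists coordinates, and 98.4% of the 14018 gene identifiers shared with the Ensembl release 115 annotation had identical coordinates. Gene names were taken from the table for 11741 genes, from the supplied symbol table for 2474 and from the table's description for 7.

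Totals were 15093162, 11070295 and 15035445 counts for RasV12 replicates 1, 2 and 3, and 12650093, 15581752 and 12859904 for GFP-i replicates 1, 2 and 3. Rows named as ribosomal RNA pseudogenes held 10.1 to 17.2% of counts and the mitochondrial chromosome 2.16 to 5.31%. No 2 libraries agreed within sampling noise. The first principal component held 58.8% of the variance and separated the genotypes, and the second held 21.8%. Reads carry no stated molecular identifiers, so floors and counting intervals cover counting error only.

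Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr and robust quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 14233 genes, 9134 were tested and 5099 had counts too low. Levels are TMM-scaled CPM with the SD over 3 libraries, fold changes are log2 RasV12 over GFP-i, and standard errors were derived from the F statistic. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. DESeq2 1.42.0 served as an alternative.

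The design, the named-gene rule, 25 gene lists and the alternatives were fixed before the data were examined. Named genes were the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between the groups, then Ras85D and ap. From each list they were the 2 members with the lowest p, and the lowest p of the other direction where members passed both ways. For DNA replication, DNA damage, G1 to S, G2 and mitosis and Ras targets 4 members were taken. Other list members are named only where a count was 5 or fewer, apart from if and mew, set in advance as a ventral and a dorsal marker, and Cat, chosen after its values were seen. The lists covered DNA replication, DNA damage and repair, apoptosis, G1 to S and G2 and mitosis genes, Ras targets and core pathway, ribosome biogenesis, ribosomal proteins, JNK, JAK/STAT, Hippo, notum, pouch, proneural, Notch, glycolysis, antioxidant, heat shock and adhesion genes, and markers of haemocytes, muscle precursors, trachea, fat body and neurons or glia. Of 485 list entries 476 were matched, and 9 are not analysed here.

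Data were simulated for RasV12 against GFP-i with 8968 genes, of which 200 changed 2-fold or 4-fold and 40 more were shifted by -0.5 log2. Changed and shifted genes all had a mean of at least 10 CPM, so detection at lower levels was not measured. Counts were drawn independently for each gene, without deviations shared between libraries. Under these settings the test called 90% of genes changed 2-fold and 98% of those changed 4-fold. Of its calls, 6.70% were unchanged genes, a share that counts calls among the 40 shifted genes as true. In the same simulated data, limma camera passed a list of 40 genes shifted by -0.5 log2 and did not pass an unshifted one. This covers the simulated lists only, since camera was not checked there at the correlations estimated in the real lists, such as 0.300 for DNA replication. The simulation therefore cannot vouch for the list calls in the real data. Alternatives were other scalings, DESeq2, limma-voom, other filters, other thresholds, a block for the replicate number, and leaving out each library. Alternatives chosen after seeing the data were a fit without ribosomal RNA and mitochondrial rows, a fit with the long-gene load as a covariate, and a fit without RasV12 replicate 3 and GFP-i replicate 2. The long-gene load is the median log2 CPM of genes over 50 kb minus that of genes under 5 kb. It was 3.16, 3.04 and 3.52 in the RasV12 libraries and 2.94, 3.63 and 3.10 in the GFP-i libraries.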

Results

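Gene expression was measured in sorted cells of the Drosophila wing imaginal disc, the larval epithelium that forms the adult wing and the dorsal thorax. One genotype expressed RasV12, a constitutively active form of the small GTPase Ras, and the control carried a construct that the labels call GFP-i. Both were driven by ap-Gal4, which is active in the dorsal compartment, under a temperature-sensitive Gal80 that held expression off for 6 days at 18 °C and released it for 3 days at 29 °C. Dorsal cells that expressed the transgenes were isolated by flow sorting, and about 150000 cells per library were profiled by 3' mRNA sequencing, which reads the 3' end of each transcript. The 6 libraries, 3 per genotype, held 11070295 to 15581752 counts. A floor of 3 counts corresponded to 0.193 to 0.271 CPM, counts scaled to the depth of the library, counting error only. The labels do not say whether the replicates came from separate groups of larvae, so p-values measure the spread between these samples. The series title names DNA synthesis and the DNA damage response as the processes of interest.

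Ras85D, the gene that RasV12 is derived from (3R, 9510561 to 9513067, dm6), stood at 54.2, 79.9 and 57.6 CPM in the RasV12 libraries and at 41.2, 38.9 and 41.2 CPM in the GFP-i libraries. It rose by a log2 fold change of 0.66 ± 0.17 (SE, n = 3 per group; edgeR adjusted p = 0.025). This call was lost without GFP-i replicate 1, 2 or 3 (adjusted p = 0.103, 0.114 and 0.150) and with scaling by library size only (adjusted p = 0.080). A 3' tag need not read the transgene, so the level of Ras85D need not check the labels. The driver gene ap was measured at 236 ± 30.3 CPM in RasV12 and 271 ± 40.98 CPM in GFP-i (SD, n = 3), a log2 fold change of -0.20 that did not pass the test (edgeR adjusted p = 0.438).

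The cytochrome P450 gene Cyp4p2 (2R, 9237512 to 9239831) rose to 89.2 ± 9.28 CPM (SD, n = 3) from 1 count in each GFP-i library, a ratio of counts of 1157 (95% counting interval 396 to 5611). The odorant-binding protein gene Obp56d had 1 count over the 3 GFP-i libraries and 899 over the RasV12 libraries, a ratio of 897 (interval 161 to 35455). CG1124 rose by 5.36 ± 0.28, CG6753 by 5.75 ± 0.43, Cyp4p1 by 6.36 ± 0.43 and hig by 5.44 ± 0.42 (log2, SE). Cyp4p1 and Cyp4p2 are similar copies that lie within hig on the other strand, so the 3 values are not independent. Besides nub and rn, the largest falls were lncRNA:CR44334 (-5.26 ± 0.36), Spn100A (-5.66 ± 0.59), asRNA:bsAS (-3.72 ± 0.22) and the ecdysone-inducible gene ImpE2 (-3.70 ± 0.53), whose call was lost without RasV12 replicate 3 and GFP-i replicate 2 together (adjusted p = 0.062). The transcript asRNA:bsAS is antisense to bs, and its reads cannot be told from those of bs where counting ignores strand. Over all genes, 1355 of 9134 tested genes changed (14.8%), 836 higher and 519 lower in RasV12 (edgeR quasi-likelihood test, adjusted p under 0.05). With scaling by library size only the split was 615 higher and 911 lower. The count was 846 without RasV12 replicate 1 and 741 without GFP-i replicate 3. At least 1 log2 unit separated the groups for 505 higher and 250 lower genes. The groups did not overlap for 33.6% of tested genes, against 10% by chance.

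Most feedback regulators and targets of Ras and MAPK signalling were higher in RasV12 cells. The antagonist sty reached 2332 ± 257 CPM against 147 ± 3.56 CPM in GFP-i (SD, n = 3), and the ETS transcription factor pnt reached 1262 ± 38.2 CPM against 62.9 ± 8.14 CPM. Their log2 fold changes were 3.98 ± 0.13 and 4.33 ± 0.14 (SE; edgeR adjusted p = 1.5e-07 for each). Another ETS factor, Ets21C, rose by 3.39 ± 0.21 and the transmembrane EGF receptor antagonist kek1 by 2.20 ± 0.17. Of the 14 tested members of this list, 12 rose and none fell (13 rose when adjusted over the list alone), while spi and vn did not pass, at 0.50 and -0.23 (spi passed without RasV12 replicate 2, adjusted p = 0.0026). The list was higher than other genes by camera (adjusted p = 5.2e-10; adjusted p = 0.24 with an estimated correlation). Of this list rho and ru overlap Ptp61F, which has more counts, on the other strand. In the core pathway 3 of 14 members rose, RasGAP1 by 2.02 ± 0.15, Ras85D as above and Egfr by 0.50 ± 0.14. None of the core members fell, the count was the same when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.292). It was higher by fry, which does not compare a list with other genes (adjusted p = 0.0093). Egfr lost its call without any library but RasV12 replicate 2 (adjusted p = 0.070 to 0.158), and 1 core member rose without GFP-i replicate 1, 2 or 3 or with scaling by library size only.

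**Figure D1:**
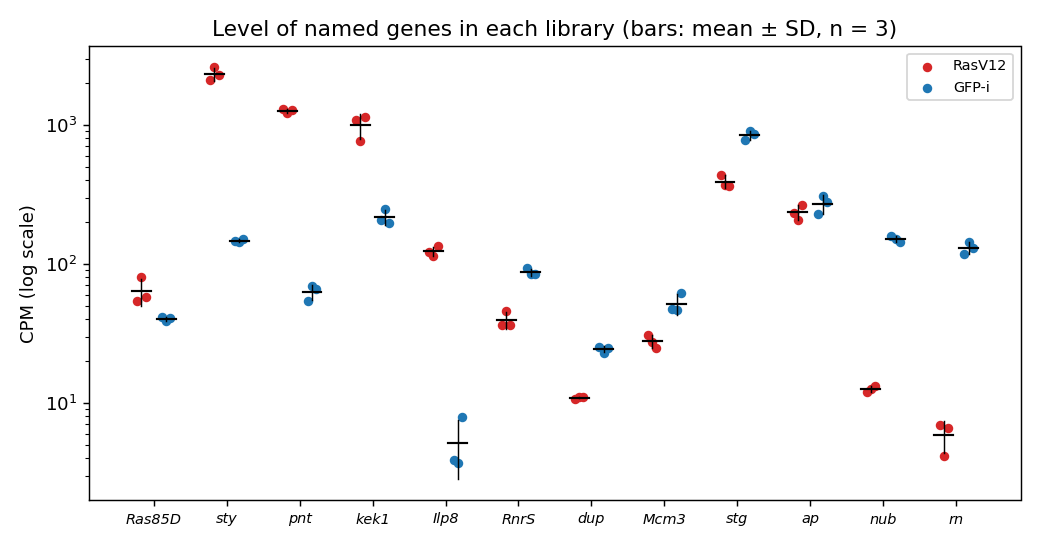
Level of 12 named genes in each library, in CPM on a log axis. Points are the 3 RasV12 and the 3 GFP-i libraries, horizontal bars the mean and vertical bars the SD. The RasV12 libraries lie above the GFP-i libraries for Ras85D, sty, pnt, kek1 and Ilp8 and below them for RnrS, dup, Mcm3, stg, nub and rn. For ap the groups overlap.

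Genes of DNA replication were lower in RasV12 cells. RnrS, the small subunit of ribonucleotide reductase, fell from 87.3 ± 5.30 CPM in GFP-i to 39.5 ± 5.53 CPM in RasV12 (SD, n = 3), a log2 fold change of -1.14 ± 0.14 (SE; edgeR adjusted p = 5.6e-04). The licensing factor dup (-1.16 ± 0.15), the chromatin assembly subunit Caf1-180 (-0.91 ± 0.14) and the helicase subunit Mcm3 (-0.89 ± 0.17) also fell. Of 44 tested members 12 fell, none rose and 32 did not pass (16 fell when adjusted over the list alone). A negative fold change was measured for 40 of them, with a list median of -0.43. The list was lower than other genes by camera (adjusted p = 7.0e-08; adjusted p = 0.47 with an estimated correlation). The number that fell was 7 without RasV12 replicate 1, 6 without RasV12 replicate 3, 6 without GFP-i replicate 3, 5 without RasV12 replicate 3 and GFP-i replicate 2 together (chosen after seeing the data), and 21 with scaling by library size only. The gene dup overlaps SRPK on the other strand, and strand use in counting is not given in the sources used here.

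Regulators of the G1 to S transition did not pass the test, in either direction, for any of the 11 members, and the same held when adjusted over the list alone. The lowest p belonged to E2f, at 406 ± 21.9 CPM in RasV12 and 318 ± 6.72 CPM in GFP-i (SD, n = 3; edgeR adjusted p = 0.063), with Dp, dap and Rbf at log2 fold changes of -0.44, 0.32 and -0.55. At an unadjusted p under 0.05 the list held 5 members, and the camera adjusted p was 0.532. DESeq2 called 1 member, Dp (adjusted p = 0.033), and limma-voom called 0; with scaling by library size only 3 fell. Without RasV12 replicate 2, E2f and Rbf passed (adjusted p = 0.026 and 0.032). With no filter 1 fell, with a filter of 10 CPM in 3 libraries 1 rose, and with the long-gene load of each library as a covariate (chosen after seeing the data) 1 rose and 2 fell. Of 33 G2 and mitosis genes only the Cdc25 phosphatase stg fell, from 847 ± 65.1 CPM to 392 ± 41.9 CPM (log2 fold change -1.11 ± 0.13, SE; edgeR adjusted p = 3.1e-04), and none rose; the count was the same when adjusted over the list alone, and 6 fell with scaling by library size only, 2 with DESeq2, and 4 with the covariate, where 1 rose; with the 10 CPM filter 2 fell and 1 rose. The next members, pim, feo and twe, stood at 0.55, -0.42 and -0.91 and did not pass, and twe overlaps EndoGI, which has more counts, on the other strand. By contrast feo passed with DESeq2, size factors, no filter, a filter of 10 CPM in 3 libraries, scaling by library size only, the covariate, and without ribosomal RNA and mitochondrial rows (adjusted p = 0.012 to 0.045). With the 10 CPM filter and the covariate pim passed (adjusted p = 0.038 and 0.033), and with scaling by library size only and the covariate twe passed (adjusted p = 0.036 and 0.037). As a group these genes were lower (camera adjusted p = 0.049), which was lost with an estimated correlation (adjusted p = 0.61 with an estimated correlation), with fry (adjusted p = 0.278) and with the covariate (adjusted p = 0.070). It was also lost without RasV12 replicate 3, GFP-i replicate 1 or GFP-i replicate 3 (adjusted p = 0.215, 0.156 and 0.151).

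Among 38 tested genes of the DNA damage response and repair, 3 rose, 1 fell and 34 did not pass, with the same counts when adjusted over the list alone. The photolyase gene phr rose by 1.19 ± 0.16 (log2, SE, n = 3 per group), and the bZIP transcription factor Xrp1 rose from 619 ± 36.6 CPM to 1033 ± 131 CPM (SD, n = 3; edgeR adjusted p = 0.0037). Corp, a p53 regulator, rose by 2.61 ± 0.47 at a low level, from 0.344 to 2.167 CPM, a call lost without RasV12 replicate 3 and GFP-i replicate 2 together (adjusted p = 0.066). The checkpoint kinase gene grp fell by 0.48 ± 0.13 (edgeR adjusted p = 0.038), a call lost without RasV12 replicate 3, GFP-i replicate 1 or GFP-i replicate 3 (adjusted p = 0.116, 0.080 and 0.089). As a group the list did not pass (camera adjusted p = 0.833), with a median of 0.08 that was -0.08 with scaling by library size only and -0.02 and -0.01 without GFP-i replicate 2 and 3. Corp overlaps CG1632 and phr overlaps Prosalpha1, each on the other strand and with more counts than the named gene, so their values are uncertain. Of 14 apoptosis genes only the TNF receptor gene wgn rose, by 0.58 ± 0.17 (edgeR adjusted p = 0.045; 0 when adjusted over the list alone), none fell, and the caspase inhibitor th stood at 0.37 (adjusted p = 0.065; 0.043 without RasV12 replicate 2). The wgn call was lost without any library but RasV12 replicate 2 (adjusted p = 0.090 to 0.197), and the apoptosis list did not pass (camera adjusted p = 0.889). None rose with other scalings, limma-voom or no filter, 2 rose with DESeq2 and 3 with the long-gene load as a covariate.

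**Figure D2:**
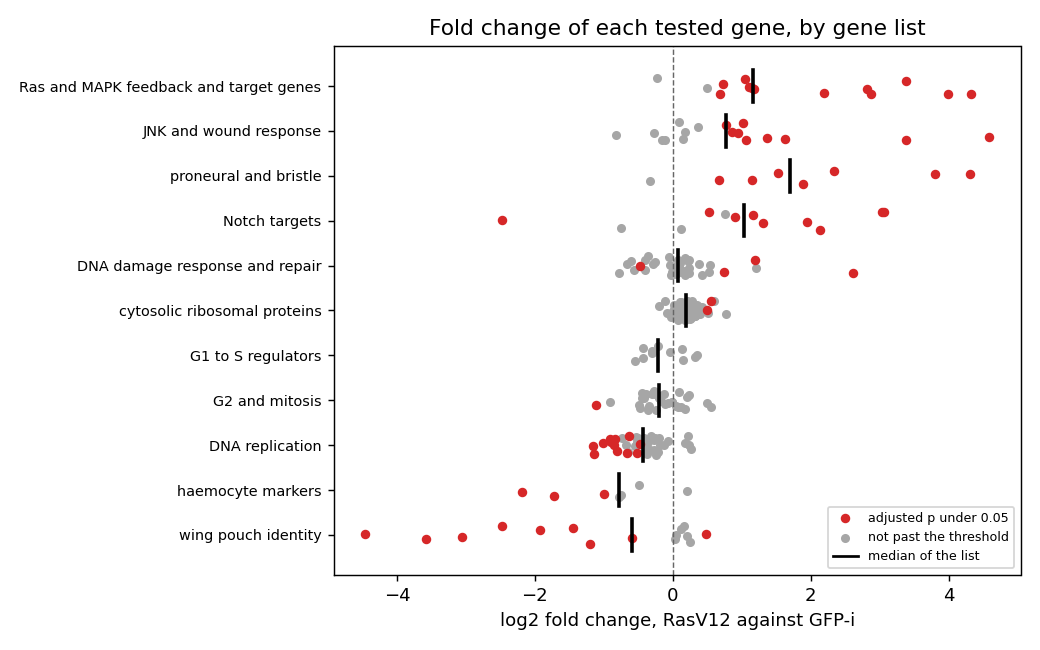
Log2 fold change of RasV12 against GFP-i for each tested gene of 11 gene lists. Each point is 1 gene, red where its adjusted p is under 0.05 and grey otherwise, and the black bar is the median of the list. Medians run from -0.78 for haemocyte markers to 1.70 for proneural and bristle genes.

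In the wound and JNK response list the relaxin-like hormone gene Ilp8 rose from 5.16 ± 2.34 CPM to 124 ± 9.82 CPM (SD, n = 3), a log2 fold change of 4.59 ± 0.28 (SE; edgeR adjusted p = 1.3e-05). Of 17 members 9 rose, with the same number when adjusted over the list alone, none fell and 8 did not pass, with a negative fold change for 4 (camera adjusted p = 0.0012; adjusted p = 0.24 with an estimated correlation). Without RasV12 replicate 3 and GFP-i replicate 2 together 5 rose. Ets21C belongs to this list and to the Ras target list. In the JAK/STAT list 4 of 9 members rose, namely the ligands upd2 (1.93 ± 0.37) and upd3 (1.57 ± 0.35), chinmo (0.78 ± 0.16) and Socs36E (0.57 ± 0.12), and zfh2 fell by 1.44 ± 0.13. When adjusted over the list alone 5 rose and 1 fell, and the list did not pass (camera adjusted p = 0.166). Without GFP-i replicate 3, 2 members rose, and upd3 and Socs36E lost their calls (adjusted p = 0.090 and 0.061). Socs36E also lost its call without GFP-i replicate 1 (adjusted p = 0.071) and chinmo without RasV12 replicate 1 (adjusted p = 0.053). Without RasV12 replicate 3 and GFP-i replicate 2 together 1 rose, and upd2 lost its call (adjusted p = 0.071). In the adhesion, polarity and matrix list 9 of 23 members rose and 2 fell (10 and 2 when adjusted over the list alone). The matrix metalloproteinase genes Mmp1 and Mmp2 rose by 1.62 ± 0.16 and 1.52 ± 0.16, while Fas3 (-0.59 ± 0.11) and LanA (-0.44 ± 0.13) fell. Only 1 member fell without RasV12 replicate 1 or 3 or GFP-i replicate 1 or 3, each of which ended the LanA call (adjusted p = 0.111 to 0.148). The list was higher by camera (adjusted p = 0.021; adjusted p = 0.49 with an estimated correlation), but not without RasV12 replicate 3 or GFP-i replicate 3 (adjusted p = 0.076 and 0.059). The Hippo list held pathway components such as ds besides targets. Of its 10 tested genes fj fell by 0.70 ± 0.15 and none rose (3 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.889). Without RasV12 replicate 2, 4 genes of this list rose and 2 fell, with DESeq2 1 and 2, and with the long-gene load as a covariate 3 and 2.

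Several wing pouch genes were lower in RasV12 cells. The POU factor gene nub (2L, 12587625 to 12628135) fell from 151 ± 7.19 CPM to 12.6 ± 0.699 CPM (SD, n = 3), a log2 fold change of -3.58 ± 0.14 (SE; edgeR adjusted p = 3.1e-07), and rn (3R, 7272617 to 7309629) fell by 4.46 ± 0.21. The Wnt ligand gene wg fell by 2.48 ± 0.23. Of 15 pouch genes 8 fell, 6 did not pass and 7 had a positive fold change, with the same number when adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.47 with an estimated correlation). Only Dll rose, by 0.48 ± 0.13 (edgeR adjusted p = 0.032), and lost that call without RasV12 replicate 1 or 3 or GFP-i replicate 1 or 3 (adjusted p = 0.069 to 0.228). In the same libraries 3 of 7 haemocyte markers and 4 of 9 muscle precursor markers fell, such as vkg (-2.18) and Him (-3.44). However, 2 muscle precursor markers rose, and that list did not pass (camera adjusted p = 0.284). Among 16 notum and dorsal genes 4 rose, Dr (0.87 ± 0.13), mirr (0.73 ± 0.12), trn (1.498 ± 0.24) and caup (0.55 ± 0.16), and 2 fell, hth (-0.78 ± 0.13) and the dorsal integrin gene mew (-0.68 ± 0.15). The counts were the same when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.866). The mew call was lost without RasV12 replicate 1 (adjusted p = 0.056), which left 1 fall, and the caup call without any library but RasV12 replicate 2 (adjusted p = 0.076 to 0.223). The integrin gene if, a ventral marker, rose by 0.78 ± 0.19, a call lost without RasV12 replicate 1 or 3 or GFP-i replicate 1 or 3 (adjusted p = 0.056 to 0.138) and with scaling by library size only (adjusted p = 0.062).

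Most proneural and Notch target genes rose. Of 8 proneural and bristle genes 7 rose and none fell, with the same number when adjusted over the list alone (camera adjusted p = 6.4e-05; adjusted p = 0.24 with an estimated correlation). Among them was phyl, at 69.4 ± 18.0 CPM against 4.93 ± 2.20 CPM (SD, n = 3). The list also held E(spl)m8-HLH, of the E(spl) complex, while other E(spl) genes were listed as Notch targets. E(spl)m8-HLH had a log2 fold change of 1.88 ± 0.15 (SE, edgeR adjusted p = 3.4e-05). Without RasV12 replicate 3 and GFP-i replicate 2 together 4 rose, and 5 rose with scaling by library size only or with the replicate block. Calls of some members were also lost when 1 library was left out. The genes ac, sc and ase overlap CG32816, which has more counts, on the other strand, so their values are not independent. Of 12 Notch targets 8 rose, led by E(spl)mgamma-HLH (3.04 ± 0.19) and E(spl)mdelta-HLH (1.94 ± 0.14), and wg fell (8 and 2 when adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.47 with an estimated correlation). The number that fell was 2 without RasV12 replicate 2, with DESeq2, limma-voom, upper quartile scaling or scaling by library size only. It was also 2 with no filter, a filter of 10 CPM in 3 libraries or the long-gene load as a covariate.

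Cytosolic ribosomal protein genes had a positive fold change in 77 of 83 cases with a median of 0.19, and 2 passed alone, RpL18 (0.49 ± 0.12) and RpS14b (0.56 ± 0.15), none when adjusted over the list alone. The list was higher by camera (adjusted p = 0.0021; adjusted p = 0.61 with an estimated correlation). It did not pass without GFP-i replicate 3 (adjusted p = 0.059) or with fry (adjusted p = 0.076). Without RasV12 replicate 2 or 3, 5 members rose, and 10 rose with the long-gene load as a covariate. RpL18 lost its call without GFP-i replicate 1, 2 or 3 or RasV12 replicate 1, and RpS14b, which has a near-identical copy, without GFP-i replicate 2 or 3 or RasV12 replicate 1 (adjusted p = 0.074 to 0.178). With scaling by library size only, the median of this list was 0.03 and the median of all genes was -0.14. Of 20 ribosome biogenesis genes Non1 rose by 1.21 ± 0.20, and Nop56 (-0.59 ± 0.14), mbm (-0.66 ± 0.17) and Nnp-1 (-0.48 ± 0.14) fell, the same when adjusted over the list alone (camera adjusted p = 0.116). None fell without GFP-i replicate 3, where Nop56 lost its call (adjusted p = 0.059), and 1 fell without RasV12 replicate 1, RasV12 replicate 3 or GFP-i replicate 2. The mbm call was lost without each of these 4 libraries (adjusted p = 0.052 to 0.106), and the Nnp-1 call without any library but GFP-i replicate 1 (adjusted p = 0.065 to 0.125). The list passed without RasV12 replicate 2 or GFP-i replicate 2 (adjusted p = 0.034 and 0.025). Of 14 glycolysis genes the lactate dehydrogenase gene ImpL3 (1.46 ± 0.15) and PyK (0.51 ± 0.13) rose and the glucose transporter gene Glut1 fell by 0.93 ± 0.21, with the same counts when adjusted over the list alone. Glut1 lost its call without RasV12 replicate 1 (adjusted p = 0.061), and PyK without RasV12 replicate 1 or GFP-i replicate 2 or 3 (adjusted p = 0.079 to 0.200), which left 1 rise. With scaling by library size only 1 rose and 2 fell. The glycolysis list had a median of 0.01 and a mean of 0.04, while camera pointed down (adjusted p = 0.889). Of 14 antioxidant genes 3 rose, Jafrac1 (1.32 ± 0.20), ref(2)P (1.14 ± 0.17) and GstE6 (1.18 ± 0.31), and none fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.116; 0.031 without GFP-i replicate 1). GstE6 lost its call without RasV12 replicate 1 or 3 or GFP-i replicate 2 or 3 (adjusted p = 0.059 to 0.161), and 1 antioxidant gene, Cat, fell without RasV12 replicate 2 (adjusted p = 0.013). None of 15 heat shock genes passed over all genes or when adjusted over the list alone, with Hsf at 0.43 and Hsp27 at -0.35. At an unadjusted p under 0.05 the heat shock list held 2 members by edgeR, and DESeq2 and limma-voom called 0. Both Hsf and Hsp27 passed without RasV12 replicate 3 (adjusted p = 0.048 for each) and with the covariate (adjusted p = 0.031 and 0.029). Hsf also passed with a filter of 10 CPM in 3 libraries (adjusted p = 0.038) and Hsp27 with scaling by library size only (adjusted p = 0.040).

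Markers of other cell types moved in both directions. Of 7 haemocyte markers 3 fell, vkg (-2.18 ± 0.35), Ppn (-0.996 ± 0.17) and Cg25C (-1.72 ± 0.32), and none rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.47 with an estimated correlation). The level of vkg was low, at 0.922 CPM in RasV12 and 4.28 CPM in GFP-i. With a filter of 10 CPM in 3 libraries only 1 haemocyte marker was tested. Of 9 muscle precursor markers Him fell by 3.44 ± 0.40, with kon, htl and zfh1 also lower, while rst and kirre rose by 1.76 ± 0.14 and 1.02 ± 0.12 (3 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.284). The gene rst overlaps kirre on the other strand, which has more counts, so these 2 values are not independent, and kon overlaps CG10176 in the same way. The zfh1 call was lost without RasV12 replicate 1 or GFP-i replicate 2 or 3 (adjusted p = 0.057 to 0.072). Of 7 tracheal markers 4 rose, obst-A (1.13 ± 0.15), btl, serp and verm, and 2 fell, Gasp (-1.83 ± 0.30) and dys (4 and 3 when adjusted over the list alone). The tracheal list had a median of 0.72 and a mean of -0.09, and did not pass (camera adjusted p = 0.689); verm lost its call without GFP-i replicate 3 (adjusted p = 0.065). Without RasV12 replicate 3 and GFP-i replicate 2 together 2 muscle markers fell and 2 tracheal markers rose. Among 8 neuron and glia markers moody rose by 0.70 ± 0.17 and brp fell by 0.91 ± 0.22 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.889), and 2 rose without RasV12 replicate 2. The brp call was lost without GFP-i replicate 2 (adjusted p = 0.051), and the moody call without RasV12 replicate 1 or GFP-i replicate 1, 2 or 3 (adjusted p = 0.058 to 0.139). Of the fat body list 2 members were tested, Lsp1beta at 0.60 and Rfabg at -1.01, and neither passed over all genes or when adjusted over the list alone. Rfabg overlaps Zyx, which has more counts, on the other strand.

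The authors' deposited table calls 446 genes higher and 252 lower at a log2 fold change of at least 1. Of its calls, 675 were among the genes tested here and 651 also passed here, 651 of them in the same direction. Passing here required no minimum fold change. At the authors' DESeq2 adjusted p under 0.05 alone, their table held 1500 of the tested genes, of which 1304 passed here. A further 51 genes passed here only. Across tested genes, which are not independent replicates, Pearson's r between the unshrunken log2 fold changes in the authors' deposited table and those of the fit was 0.999. Both came from the same counts, so this r is not a check by separate data.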

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

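The long-gene covariate, the fit without RasV12 replicate 3 and GFP-i replicate 2, and the fit without ribosomal RNA and mitochondrial rows were chosen after seeing the data; the other alternatives were planned. No called gene reversed direction in any of them. Of 73 named genes 59 passed, of which 45 kept direction and call in every refit that tested them and 14 lost the call in at least 1; the stricter thresholds were applied to counts of genes only. The count of 1355 changed genes ranged from 741 to 1521 with 1 library left out, the higher ones from 437 to 943 and the lower ones from 297 to 578; fewer samples entered these fits. With scaling by library size only 911 genes were lower. The long-gene covariate gave 2035 changed genes, 884 lower, and 1353 were shared; the cause was not tested. Leaving out RasV12 replicate 3 and GFP-i replicate 2 gave 678 (436 higher, 242 lower), with 4 samples. Stricter thresholds gave 674 (458 and 216) at an adjusted p under 0.01 and 755 (505 and 250) at 1 log2 unit, fewer by construction. With the replicate block 701 genes passed (480 higher, 221 lower). Same-numbered samples had correlations of -0.03, -0.42 and -0.11, and not every sample correlated best with its own number, so the numbers were not read as pairs. Of the 24 lists tested, 10 passed with a preset correlation and 0 with an estimated one, where DNA replication had an adjusted p of 0.467 (range over its 12 alternatives 1.0e-09 to 0.467). These 2 camera runs used the same fit and lists, but camera also tests on fewer degrees of freedom when the correlation is estimated. The Ras core pathway list had an estimated correlation of -0.022, under the preset, and its camera p still went from 0.183 to 0.230. The loss of list calls therefore cannot be credited to correlation between genes alone. The estimated correlation was 0.300 for DNA replication and 0.027 for the wound and JNK list, against the preset 0.01. Depth limits genes near the floor, and 5099 genes were not tested.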

Other observations

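The gene choices in this part and the counts of ecdysone genes and families and the tests on neighbouring genes, pouch genes and library deviations were chosen after the results they bear on were seen; the count of splits is a fixed procedure. Genes with known responses to the steroid hormone ecdysone moved in both directions. Of 19 tested members of a list of 22 such genes, 8 fell and 5 rose (edgeR adjusted p under 0.05). Among those that fell were the cuticle gene Edg78E (log2 fold change -3.71 ± 0.46, SE, n = 3 per group), Blimp-1 (-2.79 ± 0.40) and the nuclear receptor gene Hr4 (-2.27 ± 0.31). Among those that rose were Eip93F (3.25 ± 0.55), ImpL2 (1.77 ± 0.12) and ftz-f1 (0.85 ± 0.15). Without RasV12 replicate 2, Blimp-1 and Eip93F lost their calls (adjusted p = 0.055 and 0.067). Without RasV12 replicate 3 and GFP-i replicate 2 together 5 fell and 3 rose, and ftz-f1 lost its call (adjusted p = 0.069).

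Gene families defined by symbol were counted without a test, since members of a family can lie side by side. Over all tested genes 14.8% changed. Of 11 tested genes named for the E(spl) complex 9 rose and none fell. All of them belong to the Notch target or proneural lists, so this count repeats the results above. E(spl)m6-BFM did not pass (edgeR adjusted p = 0.055). It was called lower with scaling by library size only (-0.90, adjusted p = 0.031) and without RasV12 replicate 2 (-0.99, adjusted p = 0.0068). Of 34 cytochrome P450 genes 9 rose and 1 fell. Among those that rose, Cyp4p1, Cyp4p2 and Cyp4p3 lay side by side, as did Cyp6a17, Cyp6a19, Cyp6a20 and Cyp6a23. Other families were also counted, and none of 71 mitochondrial ribosomal protein genes or 19 vacuolar ATPase genes changed. Of 12 serpin genes 5 rose and 4 fell.

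The real split of the 6 libraries gave 1355 changed genes and the highest of the other splits gave 0. The 10 splits of 3 against 3 are too few for a share under 0.05, since 1 of 10 is the smallest possible.

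Changed genes lay next to each other more often than shuffled calls. Of the changed genes, 33.9% had an adjacent tested gene changed in the same direction, against 15.0% on average and at most 20.6% in 10000 shuffles (permutation p = 0.0001, the smallest they can give). A candidate explanation is reads shared between overlapping genes. Without neighbours that overlap each other the share was still 31.4%, against at most 17.6% in shuffles. Neighbours that both overlap another gene stayed in this count, such as Cyp4p1 and Cyp4p2, which lie within hig. The test therefore cannot decide how far reads shared through such a gene contributed. Runs of 3 or more included E(spl) genes, the proneural genes ac, sc, l(1)sc and ase, and Wnt4, wg and Wnt6. Of these ac, sc and ase overlap CG32816 on the other strand. Similar gene copies and shared regulation were not tested apart.

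In the wing pouch list 8 of 15 genes fell in RasV12, 7 had a positive fold change, and the list did not pass with an estimated correlation (adjusted p = 0.47 with an estimated correlation). In the same libraries 3 of 7 haemocyte markers fell and none rose, and 4 of 9 muscle precursor markers fell and 2 rose. If all members were expressed in pouch cells alone, a lower share of those cells would move the pouch list by about the change of nub (-3.58). The median over the 15 members was -0.59, above that by more than the SD over the list of 1.60. Whether members are also expressed in other sorted cells was not tested. The comparison therefore cannot decide whether a lower share of pouch cells was the whole cause. A smaller share of pouch cells, alone or together with changes within those cells, may remain. Either could follow from the genotype, the labelled difference between the groups, and they were not told apart.

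RasV12 replicate 3 and GFP-i replicate 2 deviated from their groups together, with a correlation across genes, which are not independent, of 0.58. RasV12 replicate 2 and GFP-i replicate 1 correlated at 0.45, and RasV12 replicate 3 and GFP-i replicate 1 at -0.53. On the second principal component RasV12 replicate 3 and GFP-i replicate 2 lay at 26.7 and 23.3, against -27.6 and -29.8 for RasV12 replicate 2 and GFP-i replicate 1. Deviations within a group sum to 0, so these values describe a shared axis and are not separate findings. Counts on the Y chromosome were highest within each group in RasV12 replicate 3 (86.5 CPM) and GFP-i replicate 2 (139 CPM), and were not tested as an explanation.

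For this pair of libraries a trend with gene span may contribute, since both had the highest long-gene load of their group (3.52 and 3.63), though the share of counts in genes over 50 kb was higher in RasV12 replicate 2 (9.90%) than in RasV12 replicate 3 (8.85%). Removing the span trend left a correlation of 0.51, above 0.29, which is 50% of the 0.58 before. RNA of neurons or glia was tested with the 8 listed markers, whose median deviation in these libraries lay at percentile 46.1 of 10000 lists matched on span and level. Flow sorting should remove most such cells. No explanation beyond gene span and RNA of neurons or glia was tested, and the source stays open.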
